A study of Homo sapiens with 20 samples.

How the data were processed

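The series holds 20 samples, of which 10 are NUT immunoprecipitation libraries and 10 are the matching inputs. Per the labels' protocols, chromatin was crosslinked with formaldehyde from transiently transfected cells. Retinoic acid treatment of NT2 cells came with a change to a reduced-serum medium, so the hours of retinoic acid are also hours in that medium unless the 0 h cells were kept in it, which the labels do not say. The inputs were not analysed here.

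The authors deposited a list of domains per library as a table of 6 columns without header, giving chromosome, start, end, name, score and strand. The score deposited by the authors was 1 for every domain and was not used. The submitters' processing notes name Bowtie2 2.3.4.3, deepTools 3.0.2, HOMER and bedtools and the build hg19, without their roles or settings. The peak calling and stitching parameters are not given in the sources used here. Every list begins just above 96 kb (shortest domain 96.14 to 96.9 kb), so a place without a domain may still have carried a shorter one. Lists were deposited per replicate, and no domains overlapped within a list. The deposited files hold no coverage, read counts or p-values, so depth is unknown and no interval from counts can be given. Stitching and the length minimum can both affect the measurements, since a gap in signal can divide a long domain into pieces that fall below the minimum.

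Domains on chromosomes 1 to 22 and X were used and the Y chromosome was left out. Positions are given counted from 1. Group means are given with the SD over 2 libraries. A replicated domain was formed by merging domains of both replicates that overlapped by at least 1 bp and keeping merged regions of which each replicate covered at least 50%. A replicated domain was called shared when at least 50% of it was covered by replicated domains of the other group, specific or absent when it had no base in common with a domain of either library of the other group, and partly covered otherwise. Chance overlap was estimated from 10000 circular shifts of a set along the chromosomes laid end to end (seed 1), with each chromosome's span taken as the largest domain end in any library (2988.2 Mb in all), since chromosome lengths of hg19 were not used here. Such shifts ignore assembly gaps and the clustering of active chromatin. Differences of group means and trends with time were tested by exact permutation. The similarity of replicates was tested over all pairings of the 10 libraries. Domain lengths at shared places were compared where each of the 4 libraries of a comparison had a single domain.

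The tests, the sets and the alternatives were fixed before the data were examined, apart from those named as added later. The alternatives were length minima of 150 kb and 200 kb, joining domains under 50 kb apart, autosomes only, leaving out each library, other definitions of replicated and shared domains, a replicate block and a logarithmic time scale. The regions named are among the 5 longest specific domains of each group and the 5 longest shared domains of each comparison, a rule fixed in advance. The rule also named genes from 10 gene lists, but the gene table at hand is of another build (GRCh38.p14) and coordinates were not converted, so no gene was placed in a domain and the tests on gene lists were not run. That table was used only to count protein-coding genes per chromosome.

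The shift test was tested on simulated data made with the domain lengths of the first HUES64 and dME libraries (290 and 155 domains). Of 200 pairs of sets placed at random, 6.5% had p at or below 0.05, and all planted overlaps were found (100%). Planted shared, specific and replicated domains were recovered in full (100%), and no unreplicated domain was kept (0%). These planted cases were clear by construction, since shared domains lay inside another domain, specific ones touched none and replicates differed only slightly at their ends. Their recovery checks the computation and does not measure accuracy on real lists. Replicate numbers in the labels showed no sign of pairing libraries across groups, by rough measures that cannot exclude a shared batch. Replicate 1 had more domains than replicate 2 in 3 of the 5 groups, and libraries of different groups were as similar with the same number (mean Jaccard 0.1119) as with the other number (0.1118). Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.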

Results

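BRD4-NUT is the fusion oncoprotein of NUT carcinoma, in which the acetyl-histone reader BRD4 is joined to NUT, a testis protein that binds the acetyltransferase p300. The study asked where BRD4-NUT sits on chromatin when cells of different developmental state are transiently transfected with it. Chromatin immunoprecipitation with an antibody to NUT was sequenced in 5 groups with 2 libraries each. The first 2 groups were HUES64, a human embryonic stem cell line, and mesoderm derived from it with a commercial induction medium (dME). The other 3 groups were NTERA-2 (NT2), a human embryonal carcinoma cell line, at 0 h, 4 h and 16 h of all-trans retinoic acid, which was used at 10 µM to make these cells differentiate. Each library was represented by a list of broad BRD4-NUT domains, the shortest of which spanned 96.14 kb. Read depths and domain heights were not given, so positions and lengths were the measurements. With 2 libraries per group, and no statement that they came from separate cultures, p-values from permuting libraries measure only the spread between these libraries. The p-values of circular shifts set positions against shifted positions and hold no spread between libraries. Those over chromosomes permute chromosomes and hold none either.

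HUES64 cells carried 282.5 ± 10.61 domains (SD, n = 2) over 115.68 ± 8.56 Mb. The dME cells carried 157 ± 2.83 domains over 56.84 ± 3.30 Mb. NT2 cells at 0 h carried 231 ± 22.63 domains over 105.38 ± 11.53 Mb. After 4 h of retinoic acid there were 521.5 ± 24.75 domains over 265.87 ± 11.33 Mb, and after 16 h there were 753.5 ± 27.58 domains over 376.77 ± 19.87 Mb. The median domain length was similar across groups, from 276.3 ± 17.96 kb in dME to 328.95 ± 6.58 kb at 16 h. Domains longer than 1 Mb numbered 6 and 7 in the dME libraries, 21 and 17 in HUES64, 20 and 23 in NT2 at 0 h, 71 and 67 at 4 h, and 87 and 78 at 16 h. The longest domain in any library was 4.921 Mb, in the first 16 h library.

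**Figure D1:**
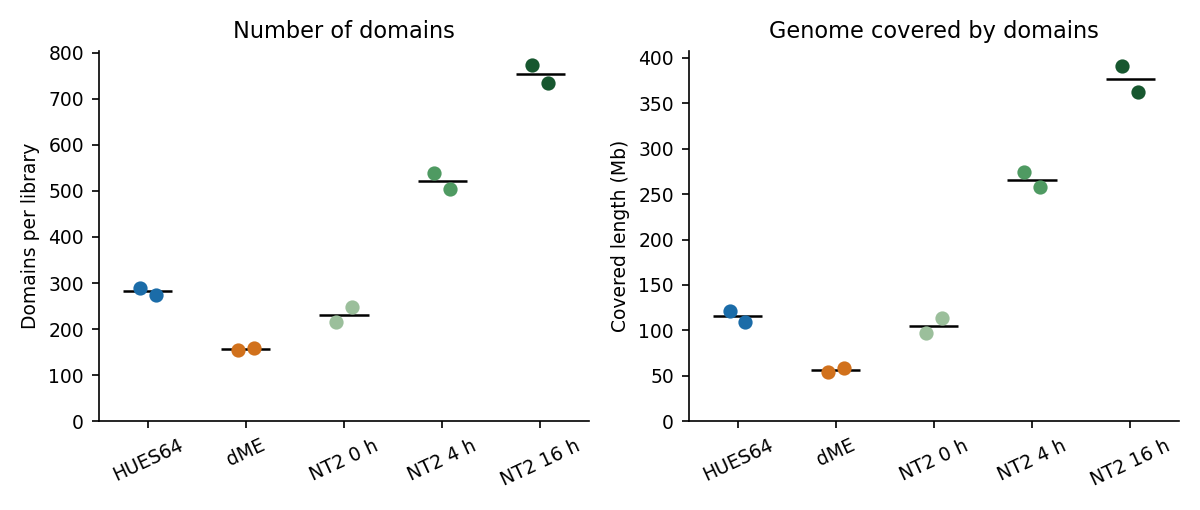
Number of domains per library (left axis panel, count) and genome length covered by domains (right axis panel, Mb) in the 5 groups; each point is a library and each line is the mean of 2. The dME libraries sit lowest (155 and 159 domains) and the 16 h NT2 libraries highest (773 and 734).

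Domain lists resembled each other within groups more than between them. Libraries of the same group had a mean Jaccard index of 0.806 (bases in both lists over bases in either), against 0.112 for libraries of different groups, with a highest value of 0.258. Of the 945 ways of pairing the 10 libraries, the true pairing gave the highest mean index (exact permutation test, one-sided, p = 0.00106, the smallest these pairings can give). The least similar replicates were those of HUES64 (0.748) and the most similar those of NT2 at 4 h (0.864). Between groups, the mean index was 0.251 for NT2 at 4 h and 16 h, 0.209 for HUES64 and NT2 at 0 h, 0.194 for NT2 at 0 h and 4 h, 0.052 for HUES64 and its own mesoderm derivative and 0.022 for dME and NT2 at 16 h. The index depends on the lengths of the lists, so these values do not rank the groups. Against shifted domains the overlap was 9.44-fold for HUES64 and NT2 at 0 h and 6.41-fold for NT2 at 0 h and 4 h. It was 3.88-fold for NT2 at 4 h and 16 h and 4.2-fold for HUES64 and dME. The highest fold possible also falls as lists lengthen, so the folds do not rank the groups either. By length, NT2 0 h libraries were covered 57.4% by 4 h libraries and 36.4% by HUES64 libraries on average. The dME domains shared 8.65 Mb with HUES64 (list of 111.19 Mb) and 9.75 Mb with NT2 at 16 h (369 Mb). A longer list meets more by chance, and dME with 16 h was not set against shifts.

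**Figure D2:**
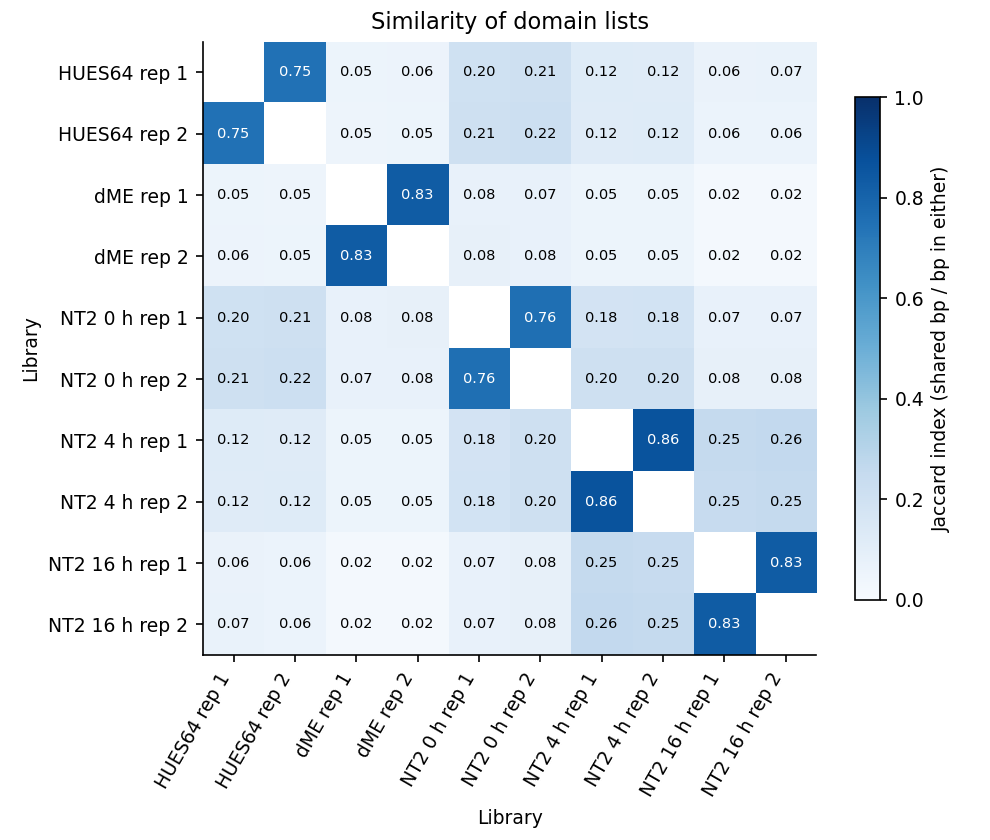
Jaccard index for every pair of the 10 libraries (both axes: libraries; color and printed value: bases in both lists over bases in either, from 0 to 1). Replicate pairs reach 0.748 to 0.864, and no pair from different groups exceeds 0.258.

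The next comparison asked how the domains of HUES64 cells changed on differentiation to mesoderm. Nearly all HUES64 domains were missing from dME, and most dME domains were at places without a HUES64 domain. Of 230 domains found in both HUES64 libraries, 206 (89.6%, 92.02 Mb) touched no domain in either dME library, 13 were shared and 11 were partly covered. Of 136 domains found in both dME libraries, 111 (81.6%, 40.92 Mb) touched no HUES64 domain, 14 were shared and 11 were partly covered.

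The longest HUES64 domain absent from dME lay on chromosome 3 from 108984002 to 111274693 (2.29 Mb, coordinates in hg19 here and below). It covered 97.4% and 79% of that span in the 2 HUES64 libraries and nothing in dME. Others lay on chromosome X from 41769885 to 43837910 (2.07 Mb), chromosome 17 from 51092967 to 52986100 (1.89 Mb), chromosome 4 from 188514690 to 190153359 (1.64 Mb) and chromosome 5 from 52235786 to 53821015 (1.59 Mb). The chromosome 17 domain was found in HUES64 only, with no overlap in any of the 8 libraries of the other groups. The longest dME domains absent from HUES64 lay on chromosome 11 from 108520686 to 109973204 (1.45 Mb), chromosome 14 from 45704803 to 47060717 (1.36 Mb), chromosome 4 from 156704415 to 157907105 (1202.7 kb) and chromosome 3 from 33901029 to 34934217 (1.03 Mb). The longest dME domain shared with HUES64 was on chromosome 5 from 122970107 to 124100507 (1.13 Mb), inside a HUES64 domain of 2.85 Mb. On chromosome 14 a dME domain from 68284963 to 69304142 (1.02 Mb) was covered in full in both HUES64 libraries.

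The 8.65 Mb shared by HUES64 and dME was more than expected for unrelated positions. Circular shifts of the domains along the genome gave a mean of 2.06 Mb, so the overlap was 4.2-fold higher (permutation by 10000 shifts, one-sided p = 0.0001, the smallest they can give). Shifts confined to domains of the other 3 groups, a setting added after the data were seen, gave 3.247-fold. That setting counts only the overlap inside those domains. The fewer domains of dME (a difference of -125.5) did not overlap the HUES64 counts, but 2 libraries against 2 cannot give an exact permutation p below 0.333. At 15 places with a single domain in each of the 4 libraries, the median length was 734.4 and 708.6 kb in HUES64 and 454 and 492.9 kb in dME. The dME domain was shorter than both HUES64 domains in both dME libraries at 11 of these places and longer at 3. Chance would give 16.7% in each direction only if the 4 libraries were interchangeable. Replicates resemble each other, so both directions can exceed that share without a shift in length.

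HUES64 and untreated NT2 cells, both pluripotent, had part of their domains in common. Of the 230 HUES64 domains, 63 (27.4%) were shared with NT2 at 0 h, 32 were partly covered and 135 were specific. Of the 187 NT2 domains at 0 h, 56 were shared with HUES64, 29 were partly covered and 102 were specific. The overlap was 35.82 Mb against 3.79 Mb for shifted domains (9.44-fold, permutation by 10000 shifts, one-sided p = 0.0001, the smallest they can give). The part inside domains of the other 3 groups was 4.643-fold against shifts confined to those domains, a setting added after the data were seen. The longest shared domain was on chromosome 5, from 122845820 to 125692392 in HUES64 (2.85 Mb) and from 122759663 to 126160518 in NT2 (3400.9 kb). Other long shared domains of HUES64 lay on chromosome X from 41769885 to 43837910, chromosome 2 from 7158417 to 8915447 (1.76 Mb) and chromosome 3 from 176645201 to 178122818 (1.48 Mb). The HUES64 domain on chromosome 14 from 98396979 to 99812330 (1.42 Mb) had no overlap in NT2 at any time. The NT2 domains on chromosome 7 from 51480516 to 53046317 (1.57 Mb) and on chromosome 3 from 180805318 to 182440396 (1.64 Mb) had none in HUES64 or dME. At 72 places with a single domain in each library, 28 were longer in both NT2 libraries and 25 were shorter (median ratio 1). Cell line and culture both differ between these groups.

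The last comparisons followed NT2 cells over the hours of retinoic acid. The mean number of domains was 2.258 times that of 0 h at 4 h and 3.262 times at 16 h, and the mean covered length was 2.523 and 3.576 times that of 0 h. Over the 6 libraries the number of domains rose with time (Pearson r = 0.938 and Spearman rho = 0.956, exact permutation p = 0.0222 for each, two-sided, over 90 arrangements). The covered length did so too (r = 0.922 and rho = 0.956, exact permutation p = 0.0222 for each). Adjusted over the 6 relations computed, these p-values were 0.0333 (Benjamini-Hochberg over exact permutation p-values). Without the 16 h libraries r was 0.993 for number and 0.995 for length over 4 libraries. With only 0 h and 4 h left, that r measures how well the groups separate and tests no trend. Without either 4 h library r was higher (0.9691 and 0.9532 for number, 0.9589 and 0.9435 for length), and its exact permutation p was 0.06667, since the reversed order of times gave as large a value and 5 libraries leave 30 arrangements. The exact permutation p of rho was 0.06667 without any single library. The trend of median domain length did not pass the test (r = 0.79, exact permutation p = 0.0778, and rho = 0.717, p = 0.1778).

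At 4 h most domains were at places without a 0 h domain, and the 0 h domains were divided between shared and absent. Of the 187 domains at 0 h, 89 (47.6%) were shared with 4 h, 22 were partly covered and 76 (40.6%) were absent. Of the 461 domains at 4 h, 321 (69.6%, 141.44 Mb) touched no 0 h domain. The longest of these lay on chromosome 2 from 163977309 to 166743804 (2.77 Mb), chromosome 6 from 111788087 to 114312525 (2.52 Mb) and chromosome 13 from 63566295 to 65869220 (2302.9 kb). The longest 0 h domains absent at 4 h lay on chromosome 2 from 7199993 to 8900187 (1.70 Mb), chromosome 7 from 51480516 to 53046317 (1.57 Mb) and chromosome 1 from 87637543 to 89173494 (1.54 Mb). The chromosome 2 region was covered in full in both HUES64 libraries. Places with a domain at both times had longer median lengths at 4 h, in a comparison of 2 libraries against 2 whose exact permutation p was 0.333, the smallest possible. At 84 places with a single domain in each library, the median was 397.9 and 411.1 kb at 0 h and 682.8 and 647.4 kb at 4 h. Of these places 57 (67.9%) were longer in both 4 h libraries than in either 0 h library, and 15 (17.9%) were shorter. Interchangeable libraries would give 16.7% in each direction, but replicates resemble each other. HUES64 and NT2 at 0 h gave 38.9% longer and 34.7% shorter in NT2 at a median ratio of 1, so 16.7% is too low a baseline. The median ratio of lengths at the 84 places was 1.27. From 4 h to 16 h, 53.8% of 169 such places were longer and 34.3% shorter (median ratio 1.07). From 0 h to 16 h, 58% of 50 places were longer and 28% shorter (median ratio 1.39). The difference of median lengths was 83.6 kb. That difference was 183.6 or 173.5 kb without a 0 h library and 46.09 kb without the second 16 h library. With a length minimum of 200 kb it was 24.01 kb. On chromosome 6 the domain from 139418640 to 142032054 at 0 h (2.61 Mb) lay in a merged region from 138727075 to 142803963 at 4 h (4.08 Mb). The first 4 h library covered 100% of that region and the second 94.8%. In the second library it was divided, since the longest domain there was 3.434 Mb.

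By 16 h more of the 0 h domains were absent than shared. Of the 187 domains at 0 h, 100 (53.5%, 44.41 Mb) touched no 16 h domain, 57 (30.5%) were shared and 30 were partly covered. Of the 649 domains at 16 h, 548 (84.4%, 283.31 Mb) touched no 0 h domain. The domain on chromosome 5 from 122759663 to 126160518, the longest at 0 h, persisted at 4 h and was absent at 16 h. The same course was followed by domains on chromosome 4 from 137984962 to 139878825 (1.89 Mb) and chromosome 3 from 180805318 to 182440396 (1.64 Mb). The longest 16 h domains with no 0 h counterpart lay on chromosome 17 from 77708544 to 80844403 (3.14 Mb), chromosome 12 from 26562771 to 29693339 (3.13 Mb), chromosome 3 from 112695561 to 115554979 (2.86 Mb), chromosome 21 from 28073247 to 30770603 (2.70 Mb) and chromosome 1 from 31383469 to 33928991 (2.55 Mb). Of their lengths, 62.2% on chromosome 12, 79.2% on chromosome 3 and 23.9% on chromosome 21 lay in domains of the first 4 h library, and none on chromosomes 17 and 1 did in either 4 h library. Places that kept a domain included chromosome 6 from 139889798 to 142026922, chromosome 1 from 58960063 to 60448430 and chromosome 14 from 68125659 to 69630481.

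**Figure D3:**
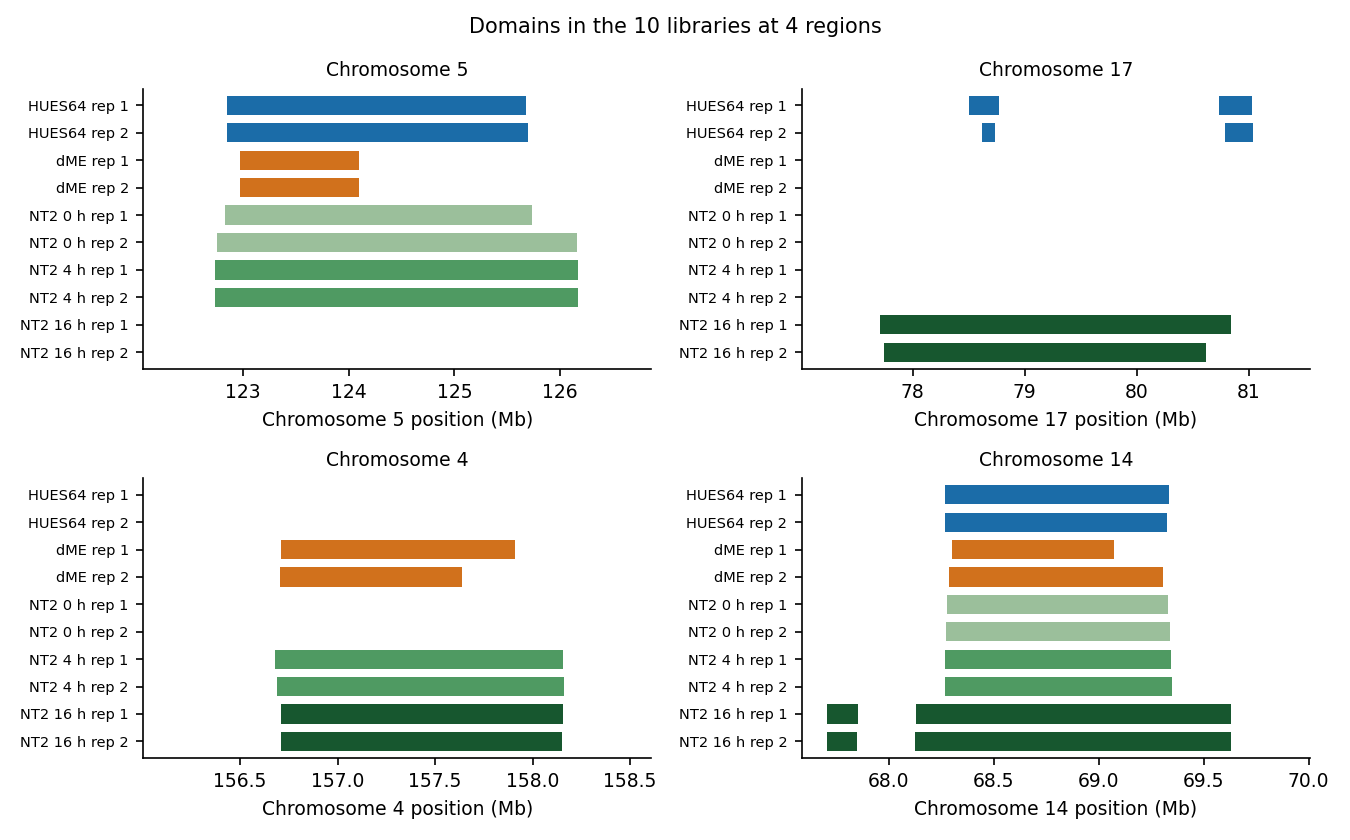
Domains in each of the 10 libraries (rows) along 4 regions (horizontal axis: hg19 position in Mb); each bar is a domain, colored by group, and the chromosome 5, 17, 4 and 14 regions show a 0 h domain absent at 16 h, a 16 h domain absent at 0 h, a dME domain absent from HUES64 and a domain found in all libraries. The chromosome 5 domain of 3400.9 kb at 0 h is absent in both 16 h libraries.

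Between 4 h and 16 h domains were again both gained and lost. Of the 461 domains at 4 h, 203 (44%) were shared with 16 h and 190 (41.2%) were absent, and 368 of the 649 domains at 16 h (56.7%) touched no 4 h domain. Of the 321 domains that 4 h had and 0 h lacked, 134 were shared with 16 h, 41 were partly covered and 146 were absent again. Of the genome in a replicated domain at any of the 3 times, 43.5% (238.18 Mb) was in a domain at 16 h alone, 19.8% (108.18 Mb) at 4 h alone, 18% (98.70 Mb) at 4 h and 16 h, 7.3% (39.85 Mb) at 0 h alone and 5.1% (27.82 Mb) at all 3 times. Overlaps in Mb exceeded shifted domains by 6.41-fold for 0 h and 4 h, 3.88-fold for 4 h and 16 h and 2.55-fold for 0 h and 16 h (permutation by 10000 shifts, one-sided p = 0.0001 for each, the smallest they can give). A setting added after the data were seen confined both lists and the shifts to places with a domain in the other 3 groups. There the overlap of 0 h and 16 h was 1.109-fold with a permutation p of 0.1099. For this pair those places include the 4 h domains, which held 27.82 Mb of the 32.13 Mb common to 0 h and 16 h. In that setting the overlap was 2.394-fold for 0 h and 4 h and 2.081-fold for 4 h and 16 h. The places differ by pair, so these folds cannot be set against each other or against the folds over the whole genome.

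**Figure D4:**
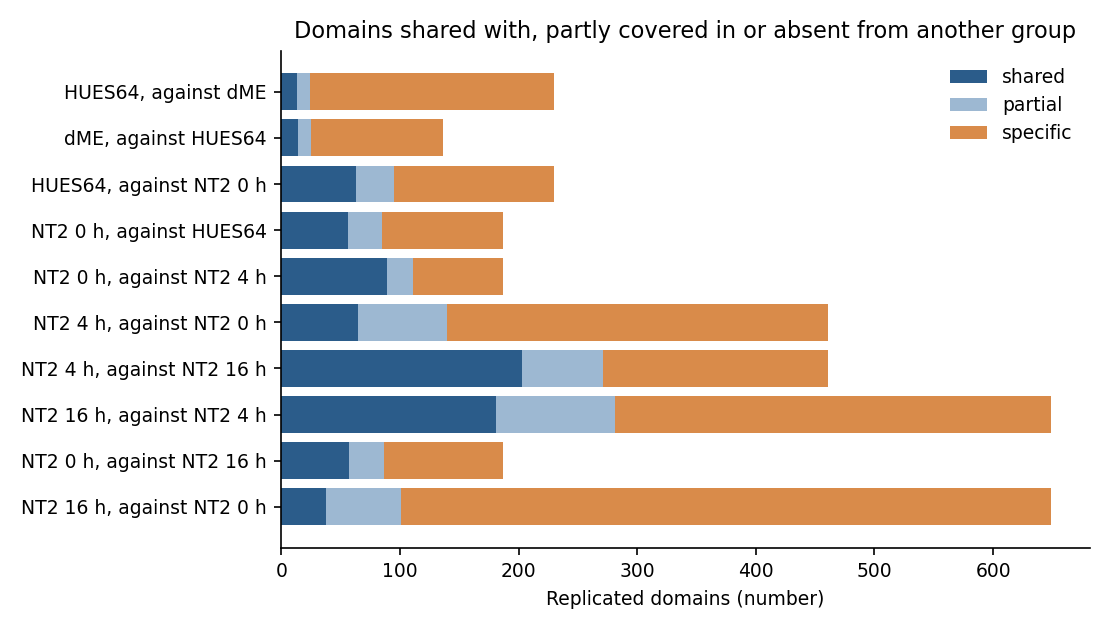
Replicated domains of each group (horizontal axis: number of domains) divided into those shared with, partly covered in and absent from (specific) the group named second. Only 13 of 230 HUES64 domains are shared with dME, and 548 of 649 domains at 16 h are absent at 0 h.

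The chromosomes took unequal parts in these changes. On chromosome 19 the NT2 libraries had 1 and 1 domains at 0 h, 0 and 0 at 4 h, and 17 and 16 at 16 h, when 15.69% of the chromosome's span lay in domains. On chromosome 17 there were 0 and 1 domains at 0 h, 7 and 7 at 4 h, and 29 and 27 at 16 h (20.03% of the span). On chromosome 22 the counts were 1 and 1, 3 and 3, and 13 and 11. Chromosome 12 was among the most covered at both later times (18.48% and 22.35%, from 6.35% at 0 h). On chromosomes 4, 13 and 18 the covered share was lower in both 16 h libraries than in either 4 h library (means 6.06% against 6.76%, 9.79% against 10.99% and 3.48% against 4.85%). These are values of 2 libraries per time, these chromosomes were chosen after their values were seen, and no test was made chromosome by chromosome.

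**Figure D5:**
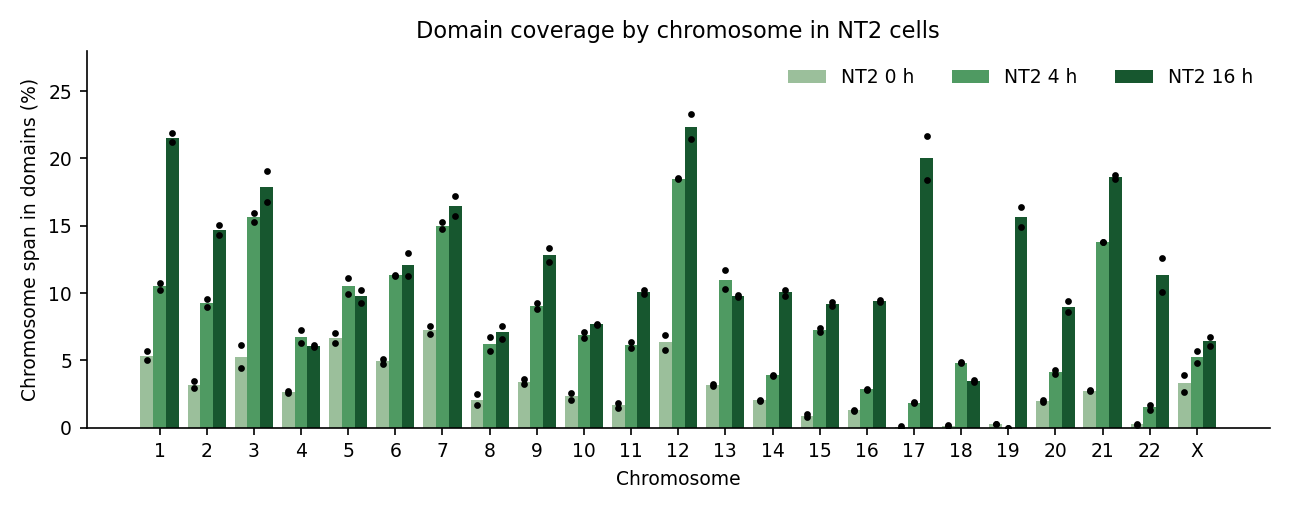
Share of each chromosome's span in domains (vertical axis, %) for chromosomes 1 to 22 and X (horizontal axis) in NT2 cells at 0 h, 4 h and 16 h; bars are means of 2 libraries and points the libraries. Chromosomes 17 and 19 go from 1.87% and 0% at 4 h to 20.03% and 15.69% at 16 h.

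The design also allows the domains gained in the 2 differentiations to be compared, since they share no library. The 111 dME domains absent from HUES64 and the 548 NT2 domains at 16 h absent at 0 h overlapped by 4.01 Mb, against 3.88 Mb for shifted domains (1.03-fold, permutation by 10000 shifts, one-sided p = 0.43). For independent changes, the overlap of the dME and NT2 16 h lists multiplied by the gained share of each gives 5.53 Mb. The result therefore depends on what it is set against. This calculation assumes that places in both lists changed as often as the rest of each list, which was not tested. HUES64 and NT2 at 0 h overlapped beyond shifts, so absence from each may be related, and these values are rough. Only 18 of the 111 touched a domain gained at 16 h. The longest stretch gained in both was on chromosome 4 from 156708088 to 157907105 (1199 kb). The 206 HUES64 domains absent from dME and the 100 NT2 domains of 0 h absent at 16 h overlapped by 8.01 Mb against 1.37 Mb for shifted domains (5.86-fold, permutation p = 0.0001, the smallest the shifts can give, and 0.0004 with Benjamini-Hochberg adjustment over the 4 combinations tested). HUES64 and NT2 at 0 h already overlapped by 35.82 Mb, and the same calculation gives 12.91 Mb for independent losses. The overlap of 8.01 Mb therefore does not show that the losses coincided. Domains gained in dME and lost by 16 h overlapped by 2.68 Mb against 0.6 Mb (4.43-fold, permutation p = 0.0008, adjusted 0.0016). The same calculation gives 3.56 Mb for them. Domains lost in dME did not overlap those gained at 16 h beyond the shifts (1.02-fold, permutation p = 0.44). They had 8.87 Mb in common, where the same calculation gives 17.81 Mb. These last 3 combinations and the values for independent changes were added after the data were seen.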

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

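The tests of explanations in this part were fixed before their results were seen, apart from the following. The comparisons of HUES64 domain lengths with shifted domains and with the shortest dME domains were chosen afterwards. The test of the difference between the 2 changes was also chosen after the data were seen. The 2 differentiations moved the number of domains in opposite directions. NT2 cells had 522.5 more domains and 271.4 Mb more covered at 16 h than at 0 h, while dME differed from HUES64 by -125.5 domains and -58.85 Mb. The difference between these changes was 648 domains and 330.24 Mb. Every library followed its group's direction, but permuting labels within each cell line gives an exact p of 0.0556 for both measures, two-sided, the smallest that 36 arrangements allow. On the log2 scale the differences were 2.56 and 2.87.

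For the gain in NT2, a more permissive call or more reads at 16 h would leave the 0 h domains nested inside the 16 h domains. Of the length of a 0 h library, at most 33.7% was covered by a 16 h library (31.4% to 33.7% over 4 pairs), which argues against that as the whole cause. Domains that merely passed the length minimum would be short, but those at 16 h without a 0 h counterpart had medians of 299.8 and 301.9 kb; a long domain that was in pieces below the minimum at 0 h is not addressed by this. Spread from neighbouring 0 h domains cannot be told apart from chance placement, since 8.6% of the domains specific to 16 h lay within 500 kb of a 0 h domain against a median of 7.9% and a 95th percentile of 10% for shifted domains. A different amount of BRD4-NUT after transfection, the change of medium and the differentiation itself stay open and untested.

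For the loss in dME, a stricter call or fewer reads alone would leave dME domains nested inside HUES64 domains. At most 16.1% of the length of a dME library was covered by a HUES64 library (14% to 16.1%). This argues against either as the whole cause. A part played by reads or calling beside a change of positions stays open, since depth is unknown. Shortening of HUES64 domains to below the length minimum met both conditions set for it in advance: domains of HUES64 without any dME overlap had medians of 282 and 259.7 kb, below the 541.7 and 457.3 kb of those with overlap, and dME domains were 34.4% shorter at shared places. Longer domains are also touched more often by chance, a flaw seen only afterwards. The length ratio of 1.92 in the first HUES64 library lay within the shifted values (median 1.59, 95th percentile 2.56). These conditions therefore cannot tell shortening from loss. Shortened by 34.4%, or to the median ratio of 0.58 at shared places, domains of 282 or 259.7 kb would stay longer than the shortest dME domains (96.9 and 96.37 kb). This argues against shortening of that size as the whole cause of the absences. Stronger shortening at those places, or division into pieces below the minimum, stays open. The change of cell state and a different amount of BRD4-NUT after transfection stay open and untested.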

How the results depend on the processing

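Shifts confined to domains of the other 3 groups and shifts within chromosomes were chosen after the data were seen; the other settings were planned. The planned settings for gene lists were not run, since no annotation of the build was used here. Replicate similarity kept its p under every setting run (0.7918 to 0.8207 without any single library). The trends of number and covered length had an exact permutation p of 0.05556 with a replicate block (r = 0.9377 and 0.9223) over 36 arrangements. They did not pass the test without either 4 h library. The block left r unchanged, and r was higher without a 4 h library. In these cases the reversed order of times gave as large a value, as it did over all 90 arrangements, and fewer arrangements raised p. As single libraries were left out, r ranged over 0.9071 to 0.9691 for number and 0.8834 to 0.9589 for length. It was lowest without the first 16 h library. The replicate block cannot move the difference of -125.5 domains between dME and HUES64, and its exact p was 0.5 in place of 0.3333; leaving out a library gave -133 to -118. With a minimum of 200 kb the specific domains numbered 137 for HUES64 against dME, 71 for dME and 66 for 0 h against 16 h, because fewer domains enter. In the same way they numbered 46 for 0 h against 4 h and 89 for HUES64 against NT2 at 0 h. HUES64 domains shared with dME numbered 20 when 1 bp counted as shared and 7 when 80% did. The overlap of domains gained in dME and at 16 h stayed near that of shifted domains, at 0.9512 with a 150 kb minimum, 0.9713 with 200 kb, 0.9071 for bases in both replicates, and 0.9341 to 1.176 without single libraries; none passed the threshold. Within domains of the other groups the overlap of 0 h and 16 h was 1.109-fold and the other overlaps were 2.081 to 4.643-fold. Those domains differ by pair, so the folds cannot be set against each other. Shifts within the domains of all 5 groups were discarded because sets placed at random gave 0.28-fold there in place of 1. No setting reversed a called result. Joining domains under 50 kb apart left the results unchanged and so gave no test of stitching. Counts have no direction to reverse, and the 1 bp and 80% rules cannot alter the counts of specific domains. Unknown depth and the length minimum limit every statement of absence.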

Other observations

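The tests in this part were chosen after the data were seen. A small core of the genome was in a replicated domain in all 5 groups. It comprised 6 stretches adding up to 2.54 Mb, or 4.6% of the dME domain length, while the domains of all libraries together covered 695.36 Mb (23.3% of the span). These stretches were chosen after their values were seen. The longest core stretch was on chromosome 14 from 68284963 to 69304142 (1019.2 kb). The others were on chromosome 1 from 59740927 to 60243961, chromosome 6 from 139889798 to 140327759, chromosome 7 from 129806523 to 130139930, chromosome 9 from 16557876 to 16726898 and chromosome 3 from 177128732 to 177205890.

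A hypothesis drawn from the chromosomes that gained most at 16 h was that gene-dense chromosomes gained more. Over 23 chromosomes, the change in covered share from 0 h to 16 h had a Spearman rho of 0.55 with protein-coding genes per Mb (permutation p = 0.0074, adjusted 0.015 over 4 comparisons) and a Pearson r of 0.54 (permutation p = 0.0065, adjusted 0.013), with rho between 0.51 and 0.59 for the 4 pairs of libraries. These p-values include the chromosomes that prompted the hypothesis and are no independent evidence for it. Without chromosomes 17 and 19, rho was 0.45 (permutation p = 0.042) and r was 0.35 (permutation p = 0.12), so the Pearson relation rests on those chromosomes and the hypothesis stays open. The step from 4 h to 16 h had a rho of 0.78 (permutation p = 3e-05, adjusted 0.00012) and an r of 0.81 (permutation p = 5e-05, adjusted 0.0002). It kept its relation without chromosomes 17 and 19 (rho = 0.71, permutation p = 0.00039, r = 0.69, permutation p = 0.00056) and without chromosome 22 as well (rho = 0.68, permutation p = 0.0012, r = 0.66, permutation p = 0.002). Chromosomes 4, 13 and 18, already seen to fall over this step, stayed in and have 4.05, 2.94 and 3.63 genes per Mb. The p-values of this step are therefore no independent evidence either. The step from 0 h to 4 h had a rho of -0.43 (permutation p = 0.04, adjusted 0.053) and an r of -0.49 (permutation p = 0.017, adjusted 0.023), and without chromosomes 17 and 19 -0.26 (permutation p = 0.25) and -0.30 (permutation p = 0.19). HUES64 to dME had a rho of 0.23 (permutation p = 0.29) and an r of 0.23 (permutation p = 0.27). Chromosomes are not independent replicates, gene counts come from GRCh38.p14 while spans come from the domain lists, and gene density goes with GC content, which was not measured.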
